A study of Homo sapiens with 5 samples.

How the data were processed

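RNA from NK92MI cells treated for 48 h with DMSO (2 libraries) or 10 µM UNC1999 (3 libraries) was sequenced. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with an NEBNext Ultra RNA kit. The authors deposited whole-number read counts per gene symbol for each library in a single table of 57221 rows. The submitters' processing notes name fastp, STAR 2.7.9, HTSeq 0.13.5, edgeR 3.34.0 and the genome build hg19, without the role or settings of each. The gene annotation, the strand setting, the RNA selection and any filter are not given in the sources used here. Reads shared by near-identical genes, and by genes that overlap on opposite strands, may therefore be split or lost.

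Columns were matched to samples by name. Totals per library were 8442908 and 8748106 in DMSO and 8644161, 8718661 and 8687863 in UNC1999. A count of 0 allows up to 3 counts, or 0.343 to 0.355 CPM, which covers counting error only and does not hold for genes with reads that were not assigned. How reads that map to several places were handled is not given in the sources used here. In the table, 222 symbols stood on more than 1 row (1939 rows), and 28 rows had names like dates, as spreadsheet programs make from some symbols. Such rows were kept for library totals. Names, GC content, transcript length and positions came from GENCODE 29 (GRCh38), which differs from the authors' hg19 and was used with no conversion of coordinates; 11258 of the 13075 tested rows (86.1%) had a GC content and length.

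Genes were kept with filterByExpr and tested with edgeR 4.0.16 in R 4.3.3: TMM factors, estimateDisp, glmQLFit and the quasi-likelihood F-test of UNC1999 against DMSO, with Benjamini-Hochberg adjustment over 13075 genes and a threshold of 0.05. TMM factors were 0.954 and 0.961 in DMSO and 1.02, 1.05 and 1.01 in UNC1999. CPM values are scaled by these factors, and log2 CPM uses a prior count of 2. Called higher or lower means an adjusted p under 0.05. The libraries of a group correlated at 0.992 (DMSO) and 0.990 to 0.993 (UNC1999) in log2 CPM, and at 0.975 to 0.981 between groups. The first principal component over 500 variable genes held 66.2% of the variance and separated the groups. Chi-square statistics per degree of freedom within groups ran from 1.87 to 9.49, so no pair agreed within sampling noise. UNC1999 replicate 2 stood apart, with 8.10 against replicate 1 and 9.49 against replicate 3. UNC1999 replicates 1 and 3 gave 1.87 and the DMSO libraries 3.30.

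Before the data were examined, 31 gene lists, the alternatives and the rule for named genes were fixed. The rule took the 10 highest and 10 lowest fold changes among called genes with an average log2 CPM of at least 3 and groups that did not overlap; 6 target and polycomb genes; 3 called members per list by smallest p, the third replaced by the best member of the other direction where the 3 went one way (with none called, the most abundant member); and the 3 smallest p per direction. Genes named outside this rule were chosen after their values were seen, as the text says beside them. The 29 lists with at least 3 tested members were tested with camera (limma 3.58.1, correlation preset at 0.01, adjusted over the 29 lists), with camera and an estimated correlation, and with fry. Both camera calls were lost with an estimated correlation.

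Alternatives were DESeq2 1.42.0 size factors in edgeR, no factors, upper-quartile factors, no filter, a stricter filter (at least 1 CPM in 2 libraries and a mean count of 50), robust dispersion, a replicate block, removal of mitochondrial and histone genes, each library left out in turn, a threshold of 0.01, glmTreat against a 2-fold change, the DESeq2 Wald test and limma-voom. After the GC trend had been seen, fits on annotated genes only and with GC and length offsets were added, and later camera with offsets and an estimated correlation together. The offsets were splines (6 degrees of freedom for GC content, 4 for length) of each library's deviation from the mean of all libraries, or from its group mean.

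The edgeR steps were tested on simulated counts for 13075 genes with 200 changed genes. In this simulation 94% of genes changed 2-fold and 66% of those changed 1.5-fold were called in the right direction. Of the calls, 5.88% were unchanged genes. The data had 4603 calls, far more than the 200 changed genes, so these shares do not give the power in the data. With a simulated GC trend in 11258 genes and no true change, 1148 genes were called without offsets and 1 with them. The simulated trend was a smooth curve in GC content alone, which splines fit easily. It does not show how the offsets act on a length trend or on true changes that follow GC content.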

Results

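Gene expression was measured by RNA sequencing in NK92MI cells, a human natural killer (NK) cell line that grows without added interleukin 2 because it carries an introduced IL2 gene. Cells were cultured for 48 h with the solvent DMSO or with 10 µM UNC1999, a small molecule that inhibits EZH2 and EZH1, the enzymes of polycomb repressive complex 2 (PRC2) that methylate lysine 27 of histone H3. The DMSO group held 2 libraries and the UNC1999 group held 3. Totals of counts assigned to genes lay between 8442908 and 8748106 per library. The comparison asks which genes respond to UNC1999 in these cells. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

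After 48 h of UNC1999, 2057 of 13075 tested genes were higher and 2546 were lower than with DMSO, mostly by less than 2-fold. A change of at least 2-fold was reached by 335 higher and 86 lower genes. The highest fold changes included VPS13C, a lipid transfer protein gene, and XRN1, a gene for a cytoplasmic RNA exonuclease (both below 2-fold once GC content and transcript length were corrected for), while PSAT1, an enzyme gene of serine synthesis, and HBEGF, which encodes a growth factor of the EGF family, were among the lowest. Integrated stress response genes fell as a group and G2/M and mitosis genes rose as a group. Both group calls were lost when the correlation between genes was estimated (adjusted p = 0.761 with an estimated correlation). Many other lists had this same value after adjustment, among them PRC2 subunits. It therefore does not set these groups apart from lists that camera did not call. The proliferation gene MKI67 rose and the transcription factor gene MYC fell, each by about 2-fold. With that correction MKI67 had a log2 fold change of 1.07 and MYC one of -0.75, below 2-fold.

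VPS13C rose from 25.9 ± 0.239 CPM (read counts scaled for library size) in DMSO to 76.3 ± 7.47 CPM in UNC1999 (mean ± SD, n = 2 and n = 3), a log2 fold change of 1.56 ± 0.13 (SE) with an edgeR adjusted p of 8.58e-11. In GENCODE 29, on build GRCh38 rather than the authors' hg19, the gene lies on chromosome 15 from 61852389 to 62060473. The other genes with the highest fold changes were LPP (1.56), PIK3C2A (1.56), XRN1 (1.54), CCDC186 (1.52), PRUNE2 (13.3 to 37.6 CPM), SMG1 (1.49), BRIP1 (1.49), LINC00342 (1.48) and NKTR (1.46, log2 unless given in CPM). All were higher in each of the 3 UNC1999 libraries than in either DMSO library. NKTR encodes a cyclophilin-related protein of NK cells, BRIP1 a DNA helicase and PIK3C2A a lipid kinase. SMG1, a kinase gene of nonsense-mediated decay, had the smallest p of all genes (edgeR adjusted p = 2.1e-11) and rose from 92.5 ± 3.8 to 260.6 ± 10.5 CPM (SD, n = 2 and n = 3). It has near-identical partial copies on chromosome 16, so its counts are uncertain.

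PSAT1 fell from 46.0 ± 2.36 to 17.6 ± 3.47 CPM (SD, n = 2 and n = 3), with a log2 fold change of -1.38 ± 0.14 (SE) and an edgeR adjusted p of 2.28e-09. GENCODE 29 places PSAT1 on chromosome 9 from 78297143 to 78330093 (GRCh38). FAM160A1 (-1.47), LINC01271 (-1.45), KCNE1 (-1.40), HBEGF (-1.39), LINC01270 (-1.17), CD101 (-1.07) and APLP2 (-1.04, all log2) also fell, with each UNC1999 library below both DMSO libraries. KCNE1 encodes a potassium channel subunit and CD101 an immunoglobulin-type surface protein. LINC01270 (50292720 to 50314922) and LINC01271 (50310711 to 50321342) overlap on opposite strands of chromosome 20 in GRCh38, and no strand setting was given, so their reads cannot be assigned to one or the other. RN7SL1, the RNA of the signal recognition particle, had a log2 fold change of -1.26 and MIR1244-2 one of -1.20; both have near-identical copies elsewhere. The RN7SL1 call was lost with robust dispersion estimates (edgeR adjusted p = 0.156) and in DESeq2 (adjusted p = 0.0792), and its value was -0.84 without DMSO replicate 1.

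**Figure D1:**
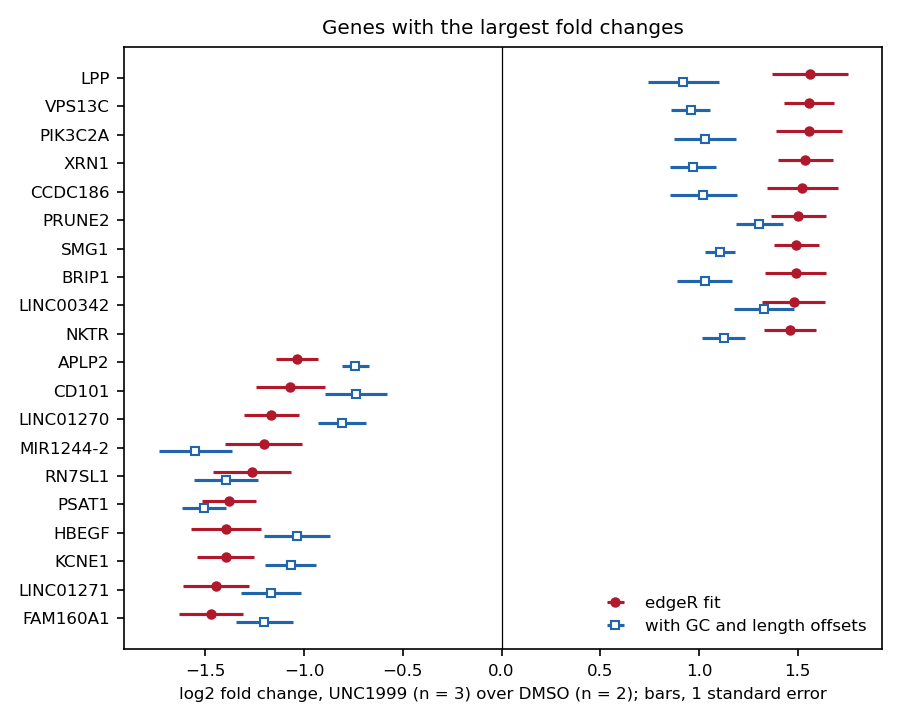
Log2 fold changes (x axis) of the 10 highest and 10 lowest genes, UNC1999 (n = 3) over DMSO (n = 2), with bars of 1 standard error. Filled points are the edgeR fit and open squares the fit with offsets for GC content and transcript length; VPS13C lies at 1.56 and 0.96, PSAT1 at -1.38 and -1.51.

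The fold changes followed the GC content of the genes. Over 10230 protein-coding genes, the median log2 fold change was 0.44 in the tenth of genes with the lowest GC content, -0.37 in the sixth decile and 0.16 in the highest decile. Of the lowest GC decile 51.2% were called higher and 4.0% lower, against 2.05% and 54.1% of the sixth. All 3 UNC1999 libraries had the gap between these deciles (0.78, 0.78 and 0.81 log2), while DMSO replicate 1 minus replicate 2 gave -0.14. By transcript length, decile medians ran from -0.12 for the shortest transcripts to 0.24 for the longest. A fit with offsets that remove both trends, added after the data were seen, called 1676 of 11258 genes higher and 2149 lower, and 122 and 53 of them by at least 2-fold. Of 4193 called genes retested there, 2578 were called again in the same direction and 3 in the opposite one. Values from that fit are given as values with offsets, and genes named only for a call in it were chosen after their values were seen. Of the 10 highest genes, VPS13C (0.96), LPP (0.92) and XRN1 (0.97) fell below 2-fold with offsets. LINC00342 (1.33) and PRUNE2 (1.31) were then the highest of the 10, before NKTR (1.12), SMG1 (1.11), PIK3C2A (1.03), BRIP1 (1.03) and CCDC186 (1.02). The lowest genes had -1.55 (MIR1244-2), -1.51 (PSAT1), -1.40 (RN7SL1), -1.20 (FAM160A1), -1.17 (LINC01271) and -1.07 (KCNE1) with offsets. The others had -1.04 (HBEGF), -0.81 (LINC01270), -0.74 (CD101) and -0.74 (APLP2).

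**Figure D2:**
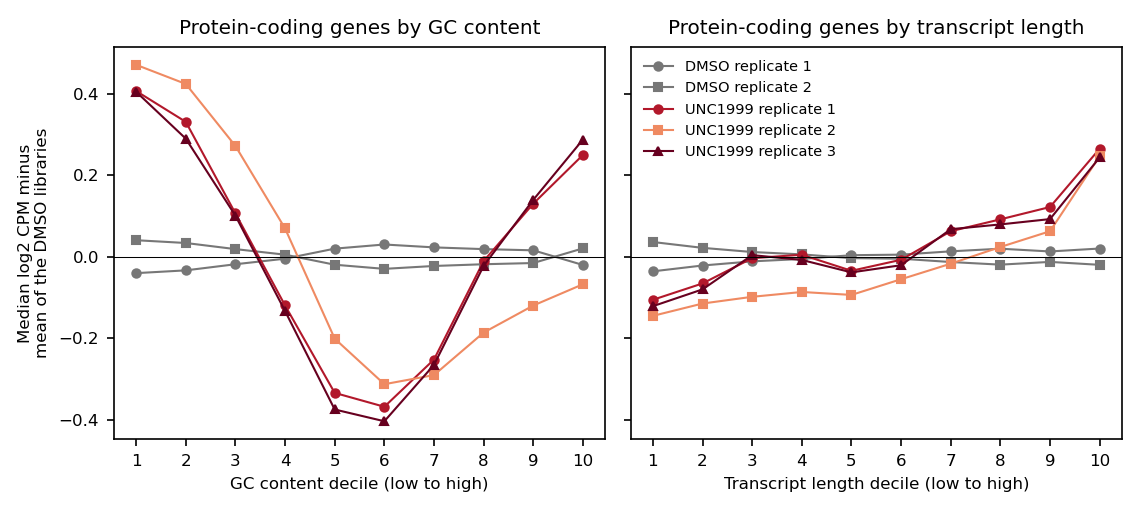
Median log2 CPM of protein-coding genes in each library minus the mean of the DMSO libraries (y axis), by decile of GC content (left) and transcript length (right). UNC1999 libraries lie at 0.41, 0.47 and 0.41 in the lowest GC decile and at -0.37, -0.31 and -0.40 in the sixth, and the DMSO libraries at -0.04 and 0.04 and at 0.03 and -0.03.

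The drug target EZH2 had 105.2 ± 0.983 CPM in DMSO and 120.6 ± 13.3 CPM in UNC1999 (SD, n = 2 and n = 3), a log2 fold change of 0.20 ± 0.11 (SE) that did not pass the test (edgeR adjusted p = 0.178). EZH2 passed with offsets (0.27, edgeR adjusted p = 0.0043), with offsets taken within groups (edgeR adjusted p = 0.0262) and without normalization factors (0.30, edgeR adjusted p = 0.0349). EZH1 had a log2 fold change of -0.31 (edgeR adjusted p = 0.048), which lost its call in 13 of 18 alternatives, among them offsets (-0.03) and the fits without DMSO replicate 1, DMSO replicate 2, UNC1999 replicate 1 or UNC1999 replicate 3 (edgeR adjusted p = 0.27, 0.136, 0.0739 and 0.189). Of 10 tested PRC2 genes, 3 were higher and 1 lower with offsets, with EZH2 and SUZ12 among the higher ones. In that fit EZH1, AEBP2 and JARID2 were not called, so the members differed from those called without offsets. Without offsets 3 were higher and 2 lower, with the same counts adjusted over the list alone. The higher ones were SUZ12, a core subunit (0.67, with offsets 0.27), AEBP2 (0.50; 0.29, edgeR adjusted p = 0.275, without DMSO replicate 1 and 0.77 without DMSO replicate 2; 0.08 with offsets) and MTF2 (0.33; -0.05 with offsets), the last chosen after its values were seen. The lower ones were EZH1 and JARID2 (-0.37, with offsets -0.13, not called), and JARID2 lost its call in 6 of 18 alternatives, among them no normalization factors (edgeR adjusted p = 0.0838), a replicate block (0.0569) and the fits without DMSO replicate 1, UNC1999 replicate 1 or UNC1999 replicate 3 (edgeR adjusted p = 0.253, 0.0797 and 0.0716). Of 16 genes for PRC1 subunits and H3K27 demethylases, 4 were higher and 3 lower, 4 and 4 adjusted over the list alone, and 2 and 4 with offsets. PHC3 (0.91, with offsets 0.30) and PCGF5 (0.68, with offsets 0.22, not called), both PRC1 subunits, rose, and PCGF3, another, fell (-0.54, with offsets -0.39). BMI1 (0.52, with offsets 0.19, not called) was higher and CBX7 (-0.48) and PHC1 (-0.43, with offsets -0.25, not called) lower, these 3 named after their values were seen. The demethylase gene KDM6A had 0.52 (with offsets 0.36), with the call lost without DMSO replicate 1 (edgeR adjusted p = 0.0641), and KDM6B had -0.05. Neither list was called as a group (camera adjusted p = 0.637 for each).

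Among developmental transcription factor genes, a class often bound by polycomb complexes, the tested members did not rise as a group. Of 60 on the list, 13 were tested, 0 were higher and 2 were lower, also adjusted over the list alone, and 0 and 1 with offsets. The lower ones were HOXA9 (-0.63 ± 0.14 SE, with offsets -0.34) and its neighbour HOXA10 (-0.52; edgeR adjusted p = 0.117 without DMSO replicate 2; -0.26, edgeR adjusted p = 0.0624, with offsets). Without offsets the median of the list was -0.17 (camera adjusted p = 0.427). With offsets it was -0.02, and the direction of the test turned from down to up (camera adjusted p = 0.972). Members with too few counts for the filter were not tested, so these values do not cover them. CDK inhibitor genes, brakes of the cell cycle, gave 0 higher and 2 lower of 5 tested, with the same counts adjusted over the list alone and, with CDKN2A (-0.19) in place of CDKN1B, with offsets (camera adjusted p = 0.564 without offsets). CDKN1B fell (-0.48, with offsets -0.12, not called) and CDKN2C had -0.34, a call lost without normalization factors (-0.23, edgeR adjusted p = 0.101), with upper-quartile factors (0.057), without DMSO replicate 2 (-0.22, edgeR adjusted p = 0.3) or without UNC1999 replicate 1 (edgeR adjusted p = 0.0579). CDKN1A had at most 2 counts in any library and was not tested.

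Integrated stress response genes, which cells switch on through ATF4 when amino acids or translation are limiting, fell in UNC1999. Of 23 tested, 12 were lower, 1 was higher and 10 were not called (13 and 1 adjusted over the list alone), with a median log2 fold change of -0.37 (camera adjusted p = 0.00021). The list was not called with an estimated correlation (adjusted p = 0.761 with an estimated correlation). PSAT1 had the lowest value (above), and the alanyl-tRNA synthetase gene AARS fell by 0.75 on the log2 scale (with offsets 0.49). The transcription factor genes ATF4 (-0.62, with offsets -0.46) and DDIT3 (-0.84, with offsets -0.49), chosen after their values were seen, also fell. The member that was higher, the cystine transporter gene SLC7A11 (0.56), was not called without DMSO replicate 1 or UNC1999 replicate 1 (edgeR adjusted p = 0.174 and 0.0689) and had -0.0012 with offsets. With offsets 14 members were lower and 1 was higher, and the median was -0.32 (camera adjusted p = 1.18e-05, and adjusted p = 0.742 with an estimated correlation).

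Unfolded protein response genes, which serve protein folding in the endoplasmic reticulum, included 9 lower and 3 higher of 19, also adjusted over the list alone (camera adjusted p = 0.148). The transcription factor gene XBP1 (-0.78, with offsets -0.42) and the disulfide isomerase gene PDIA4 (-0.71, with offsets -0.41) fell, while SEL1L, of the degradation machinery, rose (0.88, with offsets 0.41). DNAJC3 (0.76, with offsets 0.37) and HSP90B1 (0.28, with offsets 0.16, not called), named after their values were seen, were the other higher members. Lysosome and autophagy genes gave 10 lower and 1 higher of 24, and 10 and 2 adjusted over the list alone (camera adjusted p = 0.104, and 0.035 without UNC1999 replicate 3). GABARAPL1, an autophagosome protein gene, fell by 0.92 and the lysosomal membrane gene LAMP2 rose by 0.68 on the log2 scale (with offsets 0.62 and 0.41). With offsets these lists had 7 lower and 2 higher, and 7 lower and 4 higher members.

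G2/M and mitosis genes rose. Of 28 tested, 12 were higher, 3 lower and 13 not called (13 and 3 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.0022, and adjusted p = 0.761 with an estimated correlation). MKI67 rose from 317.4 ± 3.02 to 654.5 ± 57.6 CPM (SD, n = 2 and n = 3), a log2 fold change of 1.04 ± 0.11 (SE; edgeR adjusted p = 1.19e-08, with offsets 1.07). CENPF, a kinetochore gene, rose by 0.99 (with offsets 0.54). The mitotic kinase gene AURKA fell (-0.51, with offsets -0.30), as did CENPA (-0.51) and BIRC5 (-0.32), which were chosen after their values were seen; with offsets CENPA had -0.22 and BIRC5 0.0033, neither called. The 14 members with longer transcripts had a median of 0.61 (with offsets 0.40), while the 14 with shorter ones had 0.0096 (with offsets 0.04), a split made after the values were seen. The median GC content of the list was 43.3%. With offsets 12 members were higher and 2 lower, with a median of 0.15 (camera adjusted p = 0.00099, and adjusted p = 0.815 with an estimated correlation).

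DNA replication genes gave 11 lower and 2 higher of 29, 12 and 2 adjusted over the list alone, and 11 and 4 with offsets. The median without offsets was -0.15 (camera adjusted p = 0.11). MCM4, a subunit of the replicative helicase, fell from 878.5 ± 67.0 to 487.7 ± 56.9 CPM (SD, n = 2 and n = 3; log2 fold change -0.85, with offsets -0.51), and GINS1, of the same helicase complex, fell by 0.70 on the log2 scale (with offsets 0.92). POLA1, the catalytic subunit gene of polymerase alpha, rose (0.60, with offsets 0.41), and MCM6 (0.32, with offsets 0.21), named after its value was seen, was the other higher member. Replication-dependent histone genes gave 4 higher and 0 lower of 15, 2 and 0 adjusted over the list alone, and 8 and 0 with offsets (camera adjusted p = 0.124, 0.035 without UNC1999 replicate 3, and 0.0138 with offsets). With an estimated correlation the list was not called (adjusted p = 0.761, and 0.742 with offsets). The linker histone gene HIST1H1D (1.70) lost its call without DMSO replicate 2 (edgeR adjusted p = 0.0796) and without UNC1999 replicate 1 (0.97, edgeR adjusted p = 0.0627). HIST1H1E (1.36) did so without DMSO replicate 1, DMSO replicate 2 or UNC1999 replicate 1 (edgeR adjusted p = 0.141 for the last). Counts of both were low. HIST1H1D had 12 and 9 in DMSO and 67, 21 and 24 in UNC1999. HIST1H1E had 6 and 8 in DMSO and 29, 19 and 11 in UNC1999. HIST1H1C (0.29) kept its call only without UNC1999 replicate 2 among the fits with 1 library left out (edgeR adjusted p = 0.0608 to 0.412 in the others) and lost it with no filter (0.064) and a replicate block (0.0669), and HIST2H2BE (0.48, with offsets 0.78) was named after its value was seen. Ribosome biogenesis and MYC target genes gave 7 lower and 3 higher of 23, also adjusted over the list alone, and 6 and 3 with offsets (camera adjusted p = 0.637 without offsets). MYC fell from 179.7 ± 5.25 to 87.9 ± 7.41 CPM (SD, n = 2 and n = 3; log2 fold change -1.03, with offsets -0.75), ODC1, the polyamine enzyme gene, fell (-0.56, with offsets -0.22), and UTP20, a nucleolar protein gene, rose (1.30, with offsets 0.97). GNL3 (0.45) and PPAT (0.54, with offsets 0.17, not called), named after their values were seen, were the other higher members.

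**Figure D3:**
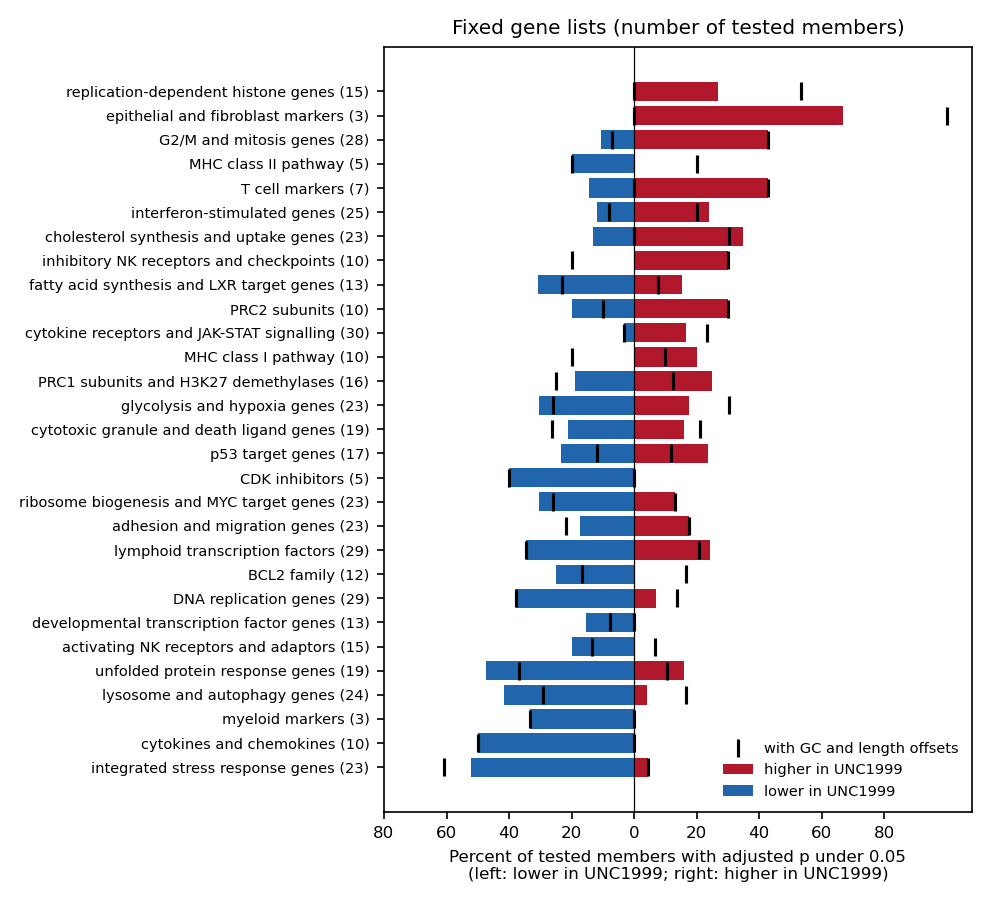
Percent of tested members of each fixed gene list called higher (red, right) or lower (blue, left) in UNC1999 at an edgeR adjusted p under 0.05, with the number of tested members in parentheses. Black marks give the percent with GC and length offsets; integrated stress response genes had 12 lower of 23 and G2/M and mitosis genes 12 higher of 28.

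Cytokine and chemokine genes gave 5 lower and 0 higher of 10, also adjusted over the list alone and, with another member in place of IL24, with offsets. Without offsets their median was -0.37, and the list passed the test without UNC1999 replicate 3 (camera adjusted p = 0.035) and with offsets (0.0109) but not with all libraries (0.107). With an estimated correlation it was not called (adjusted p = 0.761, and 0.742 with offsets). IL2 fell from 114.5 ± 6.74 to 67.6 ± 5.01 CPM (SD, n = 2 and n = 3; log2 fold change -0.76, with offsets -1.05). IL2 reads may come from the introduced gene of this line. The chemokine genes XCL1 (-0.69) and XCL2 (-0.99) fell, but they are near-identical neighbours on chromosome 1 and can exchange reads; XCL2 had -0.64 without DMSO replicate 1. IL10 (-0.58) and IL24 (-0.69, with offsets -0.35, not called), chosen after their values were seen, were the other lower members.

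The lymphoid transcription factor genes moved both ways, with 10 lower and 7 higher of 29, also adjusted over the list alone, and 10 and 6 with offsets (camera adjusted p = 0.564 without offsets). EOMES, a T-box factor gene of NK cell maturation, fell from 170.8 ± 4.63 to 102.3 ± 6.54 CPM (SD, n = 2 and n = 3; log2 fold change -0.74), and IRF8 fell (-0.88). IKZF2, the gene of the zinc finger factor Helios, rose (0.90). These 3 genes were called with offsets too (-0.46, -0.56 and 0.74). Cytokine receptor and JAK-STAT genes gave 5 higher and 1 lower of 30, also adjusted over the list alone, and 7 and 1 with offsets (camera adjusted p = 0.564 without offsets), with TGFBR1, a receptor kinase gene for TGF-beta, higher (0.67, with offsets 0.23). JAK2 (0.92) and STAT3 (-0.43, with offsets -0.17), a kinase and a transcription factor of cytokine signalling, lost their call without DMSO replicate 1 (edgeR adjusted p = 0.118 and 0.0743), and JAK2 also with offsets (0.52, edgeR adjusted p = 0.0986). IFNGR1 (0.49, with offsets 0.25, not called), STAT4 (0.45) and JAK3 (0.36), named after their values were seen, were the other higher members.

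Among activating NK receptor and adaptor genes, 3 of 15 were lower and 0 higher, 1 was lower adjusted over the list alone, and 2 were lower and 1 higher (FCGR3A, 0.61) with offsets (camera adjusted p = 0.564 without offsets). CD244, a receptor for CD48, fell (-0.55, with offsets -0.22). NCR2 (-0.30) lost its call in 10 of 18 alternatives, including offsets (-0.08) and the fits without DMSO replicate 1, DMSO replicate 2 or UNC1999 replicate 1 (edgeR adjusted p = 0.293, 0.125 and 0.0979). SH2D1B (-0.37, with offsets -0.58) lost it in 7 of 18, among them no normalization factors, upper-quartile factors, a replicate block and DESeq2 (adjusted p = 0.124, 0.0794, 0.0977 and 0.103). It was also lost without DMSO replicate 1 (-0.11), UNC1999 replicate 1 or UNC1999 replicate 3 (edgeR adjusted p = 0.68, 0.0736 and 0.0932) and had -0.57 without DMSO replicate 2. Among inhibitory receptor and checkpoint genes, 3 of 10 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.417). With offsets 3 were higher and 2 lower, namely KLRD1 (-0.71; -0.05 without offsets) and KLRC1 (-0.24; 0.0020 without offsets). CD96, a receptor for nectin-like ligands, rose (0.73, with offsets 0.57), CD200R1 rose (0.90, with offsets 0.58), and ENTPD1 had 0.52 (with offsets 0.72) with its call lost without DMSO replicate 2 (edgeR adjusted p = 0.0845). Cytotoxic granule and death ligand genes gave 4 lower and 3 higher of 19, 5 and 3 adjusted over the list alone, and 5 and 4 with offsets (camera adjusted p = 0.761 without offsets). TNFSF10, the gene of the death ligand TRAIL, rose from 6.23 ± 2.65 to 13.5 ± 0.742 CPM (SD, n = 2 and n = 3; log2 fold change 1.11, with offsets 0.86), and SERPINB9, the granzyme B inhibitor gene, fell (-0.47, with offsets -0.58). CTSC (-0.45), which encodes a protease that activates granzymes, lost its call without DMSO replicate 1 (edgeR adjusted p = 0.0928). Named after their values were seen, RAB27A (0.38) and UNC13D (0.31) were higher and SRGN (-0.40, with offsets -0.73) and STX11 (-0.33) lower. With offsets RAB27A (0.02), UNC13D (0.17) and STX11 (-0.02) were not called, so the counts of this list with offsets include members not called without them. TYROBP had 1 to 7 counts per library and KLRK1 3 to 11, and neither was tested. The annotation, the strand setting and the handling of shared reads are not given, so these counts do not by themselves show low expression.

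Adhesion and migration genes gave 4 higher and 4 lower of 23, and 4 and 5 both adjusted over the list alone and with offsets. Without offsets their median was -0.12 while the mean was 0.0091 and the test pointed up (camera adjusted p = 0.779). The integrin genes ITGA1 (1.31 ± 0.12 SE, with offsets 0.76) and ITGA4 (0.70, with offsets 0.66) rose and the chemokine receptor gene CXCR4 fell (-0.64 in both fits). Named after their values were seen, ITGB1 (0.53) and ITGB7 (0.30) were higher and S1PR1 (-0.94, with offsets -0.62), CCR1 (-0.34, with offsets -0.17) and ITGAE (-0.32) lower; ITGB1 (0.17) and ITGAE (-0.13) were not called with offsets. In the MHC class I pathway 2 of 10 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.417). The higher ones were the neighbouring genes of the peptide-trimming enzymes ERAP2 (1.16, with offsets 0.80) and ERAP1 (0.50, with offsets 0.11, not called). With offsets 1 was higher and 2 were lower, B2M (-0.57; -0.29 without offsets) and HLA-B (-0.20; -0.10 without offsets). TAP1 and PSMB8 were listed at 0 in all libraries. How reads that map to several places or to alternate haplotypes were handled is not given in the sources used here, so these zeros say nothing about expression. In the MHC class II pathway 1 of 5 was lower, HLA-DQB1 (-0.35), 0 adjusted over the list alone, and 1 lower (CTSS, -0.62) and 1 higher (CD74, 0.32) with offsets (camera adjusted p = 0.946 without offsets). The HLA-DQB1 call was lost in 11 of 18 alternatives, among them the fits without DMSO replicate 1, DMSO replicate 2 or UNC1999 replicate 3 (edgeR adjusted p = 0.338, 0.0678 and 0.156), and the value was 0.0073 with offsets. Interferon-stimulated genes gave 6 higher and 3 lower of 25, also adjusted over the list alone, and 5 and 2 with offsets (camera adjusted p = 0.761 without offsets), with MX1, an antiviral GTPase gene, lower (-0.57, with offsets -0.28). USP18 (-0.61, with offsets -0.26, not called) and IFI6 (-0.39, with offsets -0.22), the latter named after its value was seen, were the other lower members. Of the higher ones, XAF1, a pro-death gene induced by interferon, had 1.16 (with offsets 1.05), a call lost without DMSO replicate 1 (0.76, edgeR adjusted p = 0.102), and 1.74 without DMSO replicate 2.

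Cholesterol synthesis and uptake genes gave 8 higher and 3 lower of 23, also adjusted over the list alone. The camera adjusted p was 0.293, and 0.0217 with offsets, where 7 were higher and 0 lower. With an estimated correlation the list was not called (adjusted p = 0.761, and 0.742 with offsets). STARD4, a sterol carrier gene, rose from 19.0 ± 1.4 to 39.8 ± 1.36 CPM (SD, n = 2 and n = 3; log2 fold change 1.06, with offsets 0.67), and the sterol oxidase gene MSMO1 rose (0.79, with offsets 0.47). The lower ones were ACAT2 (-0.45; edgeR adjusted p = 0.0551 without DMSO replicate 1 and 0.0537 without DMSO replicate 2) and, named after their values were seen, NSDHL (-0.31) and SQLE (-0.29). With offsets none of these 3 was called (-0.12, 0.06 and -0.10). Fatty acid synthesis and LXR target genes gave 2 higher and 4 lower of 13, also adjusted over the list alone, and 1 and 3 with offsets. Without offsets the median was 0.04, the mean -0.06 and the test pointed down (camera adjusted p = 0.734). ELOVL6, a fatty acid elongase gene, rose (0.88, with offsets 0.54), and ABCG1, a sterol exporter gene, fell (-0.66, with offsets -0.41). FADS1 (-0.62, with offsets -0.33) lost its call without DMSO replicate 1 (edgeR adjusted p = 0.0998), and FASN (0.33, with offsets -0.01, not called), SCD (-0.42, with offsets -0.28) and ACLY (-0.40, with offsets -0.13, not called) were named after their values were seen. Glycolysis and hypoxia genes gave 4 higher and 7 lower of 23, and 5 and 7 adjusted over the list alone (camera adjusted p = 0.564). With offsets 7 were higher and 6 lower, and the direction of the test turned from down to up (camera adjusted p = 0.996). The glycolytic enzyme genes PGK1 (-0.65, with offsets -0.78) and HK2 (-0.53, with offsets -0.30) fell and the histone demethylase gene KDM3A rose (0.71, with offsets 0.81). PFKFB4 (0.87), PDK1 (0.60, with offsets 0.96) and PFKL (0.41, with offsets 0.29), named after their values were seen, were the other higher members.

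Of 17 p53 target genes 4 were higher and 4 lower, also adjusted over the list alone, and 2 and 2 with offsets (camera adjusted p = 0.77 without offsets). MDM2, the ubiquitin ligase gene of p53, rose (0.71, with offsets 0.28), and the DNA polymerase gene POLH and the death receptor gene TNFRSF10B fell (-0.70 each, with offsets -0.48 and -0.40). Named after their values were seen, ZMAT3 (0.65), FAS (0.54) and RRM2B (0.50) were higher and BTG2 (-0.45) and XPC (-0.44) lower. With offsets ZMAT3 (0.14), FAS (0.25), BTG2 (-0.10) and XPC (-0.16) were not called. The BCL2 family gave 3 lower and 0 higher of 12, also adjusted over the list alone (camera adjusted p = 0.417). With offsets 2 were lower and 2 higher, the latter BAK1 (0.22) and BID (0.20), while BAK1 had 0.17 and BID -0.15 without offsets. BCL2L11, the gene of the pro-death protein BIM, fell (-0.77, with offsets -0.74), as did BCL2L2 (-0.57, with offsets -0.28, not called). MCL1 had -0.30 (with offsets -0.25), a call kept without UNC1999 replicate 2 and lost without any other library (edgeR adjusted p = 0.0629 to 0.201), without normalization factors (-0.19, edgeR adjusted p = 0.157) and with upper-quartile factors (0.0908).

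Few markers of other cell types passed the filter and were tested. Of 7 tested T cell markers 3 were higher and 1 lower, also adjusted over the list alone, and 3 and 0 with offsets (camera adjusted p = 0.564 without offsets). CD6 (1.10) lost its call without DMSO replicate 1, DMSO replicate 2 or UNC1999 replicate 1 (edgeR adjusted p = 0.0758, 0.0838 and 0.0686). ICOS (0.46) lost it without DMSO replicate 1 or DMSO replicate 2 (0.0905 and 0.0998), and CD28 (-0.43) without DMSO replicate 1, DMSO replicate 2 or UNC1999 replicate 3 (0.0997, 0.162 and 0.142). CD28 was also lost without normalization factors, with upper-quartile factors, with a replicate block and in DESeq2 (adjusted p = 0.0905, 0.0575, 0.125 and 0.0967). ICOS (0.22) and CD28 (-0.08) were not called with offsets, while CD3E (0.24) and UBASH3A (0.25) were higher. TRAT1 (0.36, with offsets 0.05, not called), chosen after its values were seen, was the other higher one. Only 2 B cell markers were tested and 0 were called, with PAX5 at -0.25 (edgeR adjusted p = 0.183, and 0.0189 without UNC1999 replicate 2). Of 3 myeloid markers, S100A9, a calcium-binding protein gene, was lower (-1.05, with offsets -0.86), also adjusted over the list alone (camera adjusted p = 0.564). Of 3 epithelial and fibroblast markers, PDGFRB (0.35) and ACTA2 (1.25, with offsets 1.59) were higher, also adjusted over the list alone, and all 3, with FN1 (0.38), with offsets (camera adjusted p = 0.377 without offsets), and both lost their call without DMSO replicate 1, DMSO replicate 2 or UNC1999 replicate 1 (edgeR adjusted p = 0.0767 to 0.183 and 0.0919 to 0.204). PDGFRB also lost it without UNC1999 replicate 3 (edgeR adjusted p = 0.126) and with a replicate block (0.12). PDGFRB was abundant, with a mean of 236.0 CPM in DMSO and 299.9 CPM in UNC1999. ACTA2 had only 5 and 7 counts in the DMSO libraries and 19, 14 and 14 in the UNC1999 libraries. Mitochondrially encoded genes were listed at 0 counts in every library and 0 of them were tested; for the reason given for TAP1, these zeros say nothing about expression.

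Fewer genes were called when a DMSO library was left out, but such a fit holds 1 DMSO sample and has less power. A call lost there does not by itself show that the change rested on the library left out. Scaling moved the split, from 44.7% of calls higher to 62.9% without normalization factors and 56.5% with upper-quartile factors.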

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

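The fits on annotated genes and with GC and length offsets, alone or with an estimated correlation, were chosen after the data were seen; the other alternatives were planned. The numbers of higher and lower genes stayed within 1.5 times their values under every alternative of scaling, filter, test tool and offsets run, but ranged from 1141 to 2853 higher and 1199 to 3030 lower genes when 1 library was left out. The lowest counts came without DMSO replicate 1, which leaves 1 DMSO sample assumed to vary like the UNC1999 libraries, and the highest without UNC1999 replicate 2. Without normalization factors the median of all tested genes was 0.09 log2, against -0.01 with TMM.

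Counts of at least 2-fold changes depended most on the processing. They were 521 higher and 47 lower without factors, 215 and 13 with the stricter filter (9854 genes tested), and 122 and 53 with GC and length offsets. DESeq2 gave 32 lower, with 1775 adjusted p-values not given by the tool. A test against 2-fold itself (glmTreat) called 2 genes higher and 0 lower, while edgeR's test against no change gave 5764 genes an unadjusted p under 0.05 and DESeq2's gave 4741. Apart from the test against 2-fold, the causes of these differences were not tested.

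Of 29 gene lists, camera called 2. It called 6 with no filter, 5 with the replicate block, 5 with GC and length offsets, 0 with an estimated correlation, 0 with that and offsets together, and 2 to 5 with 1 library left out, the 5 without UNC1999 replicate 3. Fry, which does not compare a list with other genes, called 7; the cause was not tested. The integrated stress response and mitosis lists were called in each of these except with an estimated correlation.

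The replicate block called 1886 genes higher and 2136 lower, with 1 residual degree of freedom. Only 2 numbers are shared, and the deviations of same-numbered libraries correlated at 0.0658 and 0.0381. With 2 DMSO libraries the deviations mirror each other, and no reference level was set. These values therefore cannot show whether the numbers pair the samples, and the labels do not say.

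Of 100 called named genes, offsets ended 14 calls and changed the sign of SLC7A11 (-0.0012) and HLA-DQB1 (0.0073), both near 0. Leaving out DMSO replicate 1 ended 23 calls, DMSO replicate 2 16, and UNC1999 replicates 1, 2 and 3 ended 13, 0 and 8, with 0 changes of sign. In counts simulated at this depth and with these numbers of libraries, 66% of genes changed 1.5-fold were called, so smaller changes can be missed; depth and number of libraries were not varied apart.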

Other observations

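The family tests, the offsets and the tests of each explanation were chosen after the results had been seen, while leaving out libraries and the estimated correlation were planned; each explanation is a hypothesis. Gene families picked by name after the data were seen gave further groups. Genes named DUSP, SPRY or SPRED, some of which are feedback brakes on MAP kinase signalling, gave 10 lower and 0 higher of 17, with a median log2 fold change of -0.37 (camera adjusted p = 0.0111 over 7 families). DUSP5, a MAP kinase phosphatase gene, fell by 0.70 and SPRY1 by 0.55 on the log2 scale, but the lower members also included DUSP11, DUSP12, DUSP18 and DUSP28, which are atypical phosphatases. With offsets 6 members were lower and 0 higher (camera adjusted p = 0.175). Cytosolic ribosomal protein genes gave 32 lower and 1 higher of 81 (median -0.18; camera adjusted p = 0.00099), but with offsets 23 were lower and 18 higher (median 0.03; camera adjusted p = 0.375). Cytosolic tRNA synthetase genes gave 9 lower and 1 higher of 19 (median -0.0076, camera adjusted p = 0.0484), and 7 lower and 4 higher with offsets. AARS, GARS and WARS among them are also on the integrated stress response list. KARS fell by 0.73 (with offsets -0.52) while LARS rose by 0.47 (with offsets 0.21). Genes with names that start with EIF, among them kinases of eIF2 (EIF2AK2, EIF2AK3 and EIF2AK4 higher, EIF2AK1 lower), eIF4E-binding proteins (EIF4EBP1 higher, not called with offsets, and EIF4EBP2 lower), pseudogenes and an antisense RNA as well as initiation factors, gave 19 lower and 10 higher of 57 (camera adjusted p = 0.0484), proteasome genes 10 lower and 2 higher of 34 (0.0484), and numbered zinc finger genes 63 higher and 33 lower of 274 (0.0353). Chaperonin and heat shock protein genes gave 7 lower and 3 higher of 29, with a median of 0.03 and a test that pointed down (0.572). None of the 7 families passed camera with offsets, with adjusted p-values from 0.175 to 0.739. No family was tested with an estimated correlation.

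The first pattern is the dependence of fold changes on GC content, a U-shape in which GC content and transcript length together held 33.3% of the variance of fold changes over 10230 protein-coding genes. UNC1999 replicate 2 alone is argued against, since the gap between the lowest and the sixth GC decile was 0.8155 log2 without it, although it had a smaller rise at high GC (0.25, against 0.62 and 0.69 in the other UNC1999 libraries). More unspliced RNA could not be decided. The fold change fell with gene span (slope -0.05941, SE 0.00526) in a fit with GC content, length and expression as straight-line terms. The GC trend is a U-shape, so that fit did not hold GC content equal. Whether reads in introns were counted is not given either. Separate preparation of the groups cannot be told apart from the treatment: the gap between the DMSO libraries was -0.1407, and no label says which libraries were made together. An effect of UNC1999 on AT-rich and long genes therefore stays open beside a technical one.

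The second pattern is the fall of integrated stress response genes. The GC and length trend as the whole cause is argued against, since with offsets the median of the list was -0.3217. A single library is argued against as well, since the highest camera adjusted p with 1 library left out was 0.004815, and the range over these fits began at 6.55e-05. The list was not called with an estimated correlation (adjusted p = 0.761, and 0.742 with offsets), but other lists shared these values. Members of the list were not all of one direction. A batch shared by each group and an effect of UNC1999 both stay open, and no test here separates them.

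The third pattern is the rise of G2/M and mitosis genes. Whether the GC and length trend is the whole cause cannot be settled. The camera adjusted p was 0.0009926 with offsets, and 0.0016 without UNC1999 replicate 2 and no offsets. The list stayed called with each library left out. Its highest camera adjusted p in those fits lay nearer to 0.05 than that of the integrated stress response list. With an estimated correlation the list was called neither without offsets (adjusted p = 0.761) nor with them (0.815), but other lists shared these values. The offsets left a dependence on length within the list. With them the 14 longer members had a median of 0.40. The 14 shorter ones had 0.04 (bootstrap 95% interval -0.05 to 0.17). Fold change and transcript length were correlated across the 28 members with offsets (Spearman rho 0.50, permutation p = 0.0071, genes not being independent replicates). A larger share of cells in G2 or M phase cannot be told apart from other causes: 3 of 15 calls were lower, more than a share of 0.05 allows (one-sided exact binomial p = 0.0362), but with offsets 2 of 14 were (p = 0.153, the same exact test). More cells in cycle cannot be told apart either. DNA replication genes called lower outnumbered those called higher by 11 to 2 (exact binomial p = 0.0225). With offsets they did so by 11 to 4 (p = 0.1185, exact binomial test). All these binomial tests treat genes as independent trials, which genes measured in the same libraries are not. The share of 0.05 was a chosen limit and not a measured share of cells.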
